A study of Homo sapiens with 4 samples.

How the data were processed

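Gene expression was measured on 4 Affymetrix human transcriptome arrays, 1 for each combination of cell line (SUM159 or MDA-MB-231) and state (uninduced control or miR-100 induced). Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cDNA was made from it with the Affymetrix WT terminal labelling kit. The authors' deposited table holds 1 log2 signal per probeset and array, with values from 1.54 to 19.86. Affymetrix Expression Console and Transcriptome Analysis Console were used, per the submitters' processing notes; their versions, the summarisation algorithm and the normalization are not given in the sources used here. The array medians lay between 4.00 and 4.07, so the arrays were on a common scale as deposited, and no further scaling was applied. Because the normalization is unstated, a shift shared by most genes of 1 array could have been removed before deposit.

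The table holds 70523 probesets. The platform annotation gave exactly 1 gene symbol to 23781 of them, several symbols to 1543 and none to 45199. Probesets with several symbols or none were not used for genes. Of 21545 single-symbol probesets with a gene ID, 21497 matched the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and was used for names and gene types only. No coordinates are given, since the build behind the probesets is not given in the sources used here. Where a gene had several probesets, the brightest over the 4 arrays was taken. Of 22465 named genes, 14418 with a mean log2 signal at or above 4.035, the median over all probesets, were kept, and 11883 of these are protein coding by their gene ID. Paralogs that can share probes, such as FAM72C and FAM72D, the metallothioneins, HLA-DRB genes and pseudogenes, are uncertain as single genes.

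Within a line there was 1 array per group, so induced minus control is a log2 difference with no replicate check and no test. Genes at or past 1.5-fold (0.585 on the log2 scale) were counted in each direction. Over both lines, limma (lmFit and eBayes) was fitted with cell line as a block, which leaves 1 residual degree of freedom. The difference between the lines was fitted with treatment as a block. P-values were two-sided and were adjusted by Benjamini-Hochberg over all 14418 genes, with a threshold of 0.05. The labels do not say that the arrays came from separate cultures. In both fits the residual is how far the 2 lines differed in their response to induction. P-values of single genes therefore measure that difference, and not a spread of replicate arrays or cultures.

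The 24 gene lists, the groups, the tests, the signal filter, the rule for named genes and most alternatives were set before the data were examined. A list with at least 5 kept members was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists that qualified. Camera with an estimated correlation and fry were run beside it. At the preset, camera sets the statistics of a list's members against those of all other genes and treats members as nearly independent. A small p from it therefore does not measure agreement between the lines or between replicate arrays. With 1 residual degree of freedom the estimated correlation is coarse. Each list's median within a line was also placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. The mitochondrially encoded list had 0 members with a probeset of their own and is not analysed here. List members with no probeset of their own under these rules are not analysed here.

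The genes named in the text follow a fixed rule. It takes the miR-100 locus, the 12 highest and 12 lowest differences per line, and up to 12 genes per direction past 1.5-fold the same way in both lines, ranked by the smaller of the 2 absolute differences, because fewer than 10 genes passed the adjusted threshold. It also takes up to 4 members per list, the 10 most different genes per direction between lines, and up to 6 genes past 1.5-fold in opposite directions. Small RNA genes, unnamed loci, antigen receptor segments and sex-linked markers were left out of the ranked parts. PLK1, IGF1R, THAP2, MBNL1, ATF4, STC2 and the MAPK and YAP genes were chosen after their values or those of related genes were seen.

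The limma procedure was tested on simulated data of the same 14418 genes, with 200 changed by the same amount in both lines. It recovered 0% of them at 2-fold, 82.5% at 4-fold and 97.5% at 16-fold, with 0.1, 9.4 and 14.3 false calls per run. This does not carry over to responses that differ between lines: MIR100, higher by 11.62 and 9.18, had a limma adjusted p of 0.918. A lack of calls therefore does not speak against large changes. In 50 simulated lists of 27 genes shifted by -0.25, camera with the preset correlation called 100%, the estimated correlation 0% and fry 2%, and 0% of unshifted lists were called by the preset. Genes were drawn independently, so these runs do not show how the preset behaves for lists whose members vary together. Alternatives were quantile normalization, centring each array on its median, no signal filter, a cutoff at the 75th percentile (5.935), averaging probesets, a 2-fold count, eBayes with trend or robust, no block, leaving out each array, and an adjusted threshold of 0.1. Restricting to protein-coding genes, leaving out MIR100 and leaving out the 3 lowest targets were chosen after seeing the data. Predicted seed-site targets were not analysed here, as that needs transcript sequences. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.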

Results

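Transcriptomes were profiled in SUM159 and MDA-MB-231, established lines derived from triple-negative breast cancer. Each line had been transduced with a lentiviral plasmid from which miR-100, a microRNA of the miR-99/100 family, is expressed when a tetracycline-type drug is added. Cells were compared after 1 week with or without the drug, to ask which transcripts differ when miR-100 is overexpressed. The series' design text names SUM149 where the sample labels name SUM159; the sample labels are followed here. The drug is called doxycycline in some labels and tetracycline in others. The data comprise 4 arrays, 1 for each line in each state, and there were no replicates of any group. Across all probesets, the control and induced arrays correlated at 0.993 in SUM159 and 0.996 in MDA-MB-231, against 0.958 to 0.959 between lines; these are correlations across probesets, which are not independent replicates. The number of arrays limits the precision. Among probesets below the signal cutoff, the induced minus control differences had a spread (SD from the median absolute deviation) of 0.19 log2 units in SUM159 and 0.18 in MDA-MB-231.

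The induced gene was examined first. The MIR100 probeset (TC11002385.hg.1) had a log2 signal of 6.56 in control and 18.18 in induced SUM159 cells, higher by 11.62. In MDA-MB-231 the signal was 8.11 in control and 17.29 in induced cells, higher by 9.18. It was the highest difference of all named genes in each line, and both arrays labelled induced carried it. The probeset signal does not tell mature miR-100 from a longer transcript of the construct, so the rise of the mature microRNA is not known here. The host transcript MIR100HG was higher by 0.35 and 0.19 in SUM159 and MDA-MB-231. The neighbouring microRNA gene MIRLET7A2 was higher by 0.94 in SUM159 and 0.10 in MDA-MB-231. MIR125B1 lay below the signal cutoff, at 3.13 to 3.36 on the 4 arrays. In limma over both lines, the mean difference of MIR100 was 10.40 ± 0.65 (SE, 2 lines), with an adjusted p of 0.918 among 14418 genes.

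**Figure D1:**
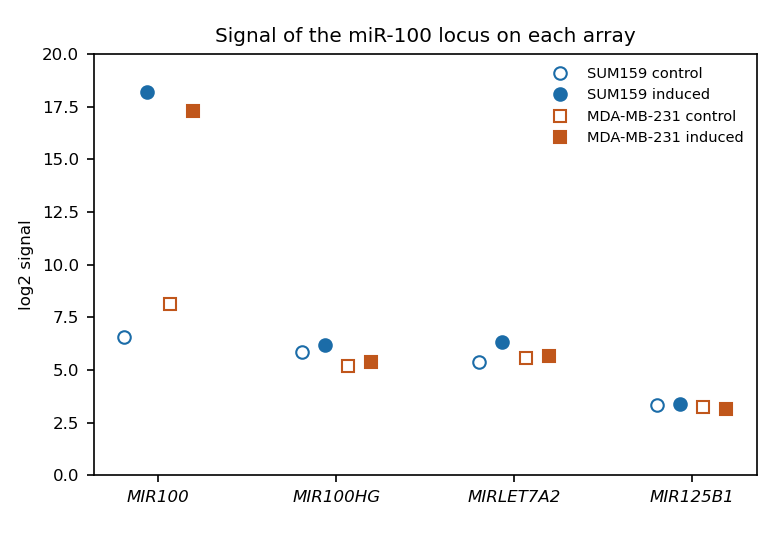
Log2 signal (vertical axis) of the 4 genes of the miR-100 locus on each of the 4 arrays, with 1 point per array, open for control and filled for induced. MIR100 lies at 18.18 and 17.29 on the induced arrays and at 6.56 and 8.11 on the controls, whereas MIR125B1 stays between 3.13 and 3.36.

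In SUM159, the differences among the genes that were ranked reached 3.10 log2 units upward and -2.64 downward. PPIF, the mitochondrial cyclophilin D, was higher by 3.10 log2 units, and the crosslinking enzyme gene TGM2 by 2.51. The chemokine gene CXCL8 (interleukin 8) was higher by 2.48, the immediate early transcription factor gene EGR1 by 2.36, CD274, which encodes the immune checkpoint ligand PD-L1, by 2.28, and the MAPK phosphatase gene DUSP5 by 2.18. The calcium channel gene TRPC4 (8.10 in control and 10.10 in induced cells), the Fc receptor gene FCAR (1.98), FOXF1 (1.91), CRISPLD2 (1.87), IRAK2 of interleukin 1 signalling (1.76) and the matrix glycoprotein gene TNC (1.74) completed the 12 highest. The endoplasmic reticulum chaperone gene CLGN had the lowest difference, at -2.64. It was followed by the cytochrome P450 gene CYP4B1 (-2.58), the receptor tyrosine kinase gene ROS1 (-2.52), the interleukin 33 receptor gene IL1RL1 (-2.39) and the adhesion gene CADM3 (-2.33). PLAC8 (-2.08), the hemidesmosome integrin gene ITGB4 (-1.96), CMKLR2 (-1.89), the netrin receptor gene UNC5B (-1.80), the sodium channel gene SCN9A (-1.79), SULT1E1 (-1.76) and GABRG1 (-1.68) completed the 12 lowest. For these 24 genes the MDA-MB-231 differences lay between -0.24 and 0.57. TRPC4, FOXF1, ROS1, SULT1E1 and GABRG1 lay below the signal cutoff on both MDA-MB-231 arrays, and IL1RL1 lay near it (3.95 and 4.08). A fall of these genes could not have been seen in that line.

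Of 14418 kept genes, 570 were at or past 1.5-fold higher and 432 lower in induced SUM159 cells, of which 78.2% are protein coding; after quantile normalization the counts were 471 higher and 515 lower, so which direction had more genes depends on the scaling. The list of NF-kB and inflammatory cytokine genes (camera over both lines, adjusted p = 0.106) had a median difference of 0.25 over 19 members, at percentile 99.985 of matched random lists. CXCL8, the NF-kB feedback inhibitor gene TNFAIP3 (1.26), CXCL2 (0.86) and NFKB2 (0.77) were the 4 members past 1.5-fold, all higher. Mesenchymal and matrix genes had a median of 0.18 over 23 members, at the 98.6th percentile, and a camera adjusted p of 0.664 over both lines. Of these, 6 were past 1.5-fold higher, among them TNC, SPARC (1.59) and the fibronectin receptor gene ITGA5 (1.53), and 3 were past it lower, among them the collagen crosslinking enzyme gene LOX (-1.46). No test was possible with 1 array per state, and at 2-fold the counts were 105 higher and 84 lower.

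In MDA-MB-231 the differences of genes other than MIR100 were smaller. The tetraspanin gene CD9 had the highest of these among the genes that were ranked, at 1.33, followed by OSTF1 (1.12), EBAG9 (1.08), FAM72D, NAP1L3 and the signal recognition particle gene SRP9 (1.06 each). HLA-DRB1 (1.02), FAM72C (1.01), CAVIN4 (1.00), the chemokine gene CCL20 (1.00), the inositol phosphate kinase gene IPMK (0.99) and APIP (0.96) completed the 12 highest. The probesets of FAM72C and FAM72D cannot be separated with certainty, since the genes are near-identical copies. The lowest differences among the ranked genes were those of PCDH9-AS1 (-0.98), the mitochondrial carrier gene SLC25A23 (-0.97), the homeobox gene HOXC13 (-0.94), the vacuolar ATPase accessory gene ATP6AP1 (-0.91) and the telomerase RNA gene TERC (-0.87). The cytokine genes IL24 (-0.82) and LIF (-0.80), OR8B12 (-0.82), the RNA-binding protein gene RAVER1 (-0.81), the histone gene H2BC11, the glycogen-targeting phosphatase subunit gene PPP1R3C and the uncoupling protein gene UCP2 (-0.79 each) completed the 12 lowest. CAVIN4 and CCL20 started from control signals of 4.39 and 3.61, near or below the cutoff.

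In this line 244 genes were at or past 1.5-fold higher and 113 lower, of which 66.9% are protein coding. Together they were 2.48% of kept genes. Of probesets below the signal cutoff, 2.34% were past 1.5-fold, so the count lay near this background share. In SUM159 the 2 shares were 6.95% and 3.39%. Cholesterol synthesis genes had a median of -0.17 over 19 members, at the 0.1st percentile of matched lists, while in SUM159 their median was 0.07, at the 65.3rd percentile. DHCR7, which encodes the last enzyme of the pathway, stood at -0.42, the transcription factor gene SREBF2 stood at -0.39, MSMO1 at -0.35 and the sterol transfer gene STARD4 at 0.43; 0 members were past 1.5-fold. The 5 kept basal epithelial genes had a median of -0.23, at the 1.26th percentile, with SFN at -0.64, TRIM29 at -0.31, SERPINB5 at -0.23 and EGFR at 0.13. This median is the value of SERPINB5, whose signals in this line (4.01 and 3.78) lay below the cutoff. The basal keratin genes KRT5, KRT14, KRT15 and KRT16 were not kept, so the list says little about a basal programme. There was no test here either. The 113 lower genes became 69 with the signal cutoff at the 75th percentile and 58 among protein-coding genes, and at 2-fold 15 were higher and 6 lower.

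Few genes differed the same way in both lines. ATP6AP1 stood at -1.62 in SUM159 and -0.91 in MDA-MB-231, and PPP1R3C at -1.40 and -0.79. The ubiquitin ligase gene RNF144B had differences of -0.91 and -0.78, and SMARCD1, which encodes a SWI/SNF chromatin remodelling subunit, of -0.89 and -0.73. The small phosphatase genes CTDSP2 (-0.71 and -0.73) and CTDSPL (-0.99 and -0.65) were both among them, as were SYNE1-AS1 (-0.77 and -0.66), the N-myristoyltransferase gene NMT1 (-0.67 and -0.65), DNAJC11 (-0.93 and -0.63), the cationic amino acid transporter gene SLC7A1 (-0.67 and -0.62) and SFT2D2 (-0.80 and -0.61). Genes higher in both lines included SLC25A36 (0.83 and 0.77), the RNA polymerase III subunit gene POLR3G (0.86 and 0.75), ENDOD1 (0.76 and 0.72), PGM2L1 (1.47 and 0.71), ZNF92 (0.70 and 0.67), the adhesion receptor gene CXADR (0.95 and 0.66), NT5E, which encodes the ectonucleotidase CD73 (1.22 and 0.66), and the membrane-curvature gene FNBP1L (1.40 and 0.63). FAM72D (0.65 and 1.06), the pseudogenes FABP5P7 (0.88 and 0.63) and HSP90AA4P (0.63 and 0.62), and a probeset that carries the symbol NDUFB2 without a gene ID (1.42 and 0.78) were also higher, and each is uncertain as a single gene.

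In all, 22 genes, MIR100 among them, were past 1.5-fold higher in both lines and 12 lower, where independent lists would share 9.65 and 3.39. A further 17 went opposite ways, 5 of them higher in SUM159 and 12 higher in MDA-MB-231, against 4.47 and 7.31 for independent lists. After quantile normalization the same-way counts were 17 higher and 16 lower, and after centring 18 and 15. The differences of the lines correlated across genes with a Pearson r of 0.111 and a Spearman rho of 0.0211; without MIR100 the Pearson r was 0.0268. Genes are not independent replicates, and no p is given. With limma over both lines, 0 of 14418 genes passed an adjusted p of 0.05, and 373 higher and 183 lower genes had an unadjusted p under 0.05. Together these were a smaller share of the genes than the 0.05 that such a threshold passes on average when no gene differs. No other setting of limma made a call. ATP6AP1 had a mean difference of -1.26 ± 0.22 (SE), SMARCD1 of -0.81 ± 0.12, CTDSP2 of -0.72 ± 0.11, SLC25A36 of 0.80 ± 0.12 and NT5E of 0.94 ± 0.19, each over 2 lines and each with a limma adjusted p of 0.918.

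**Figure D2:**
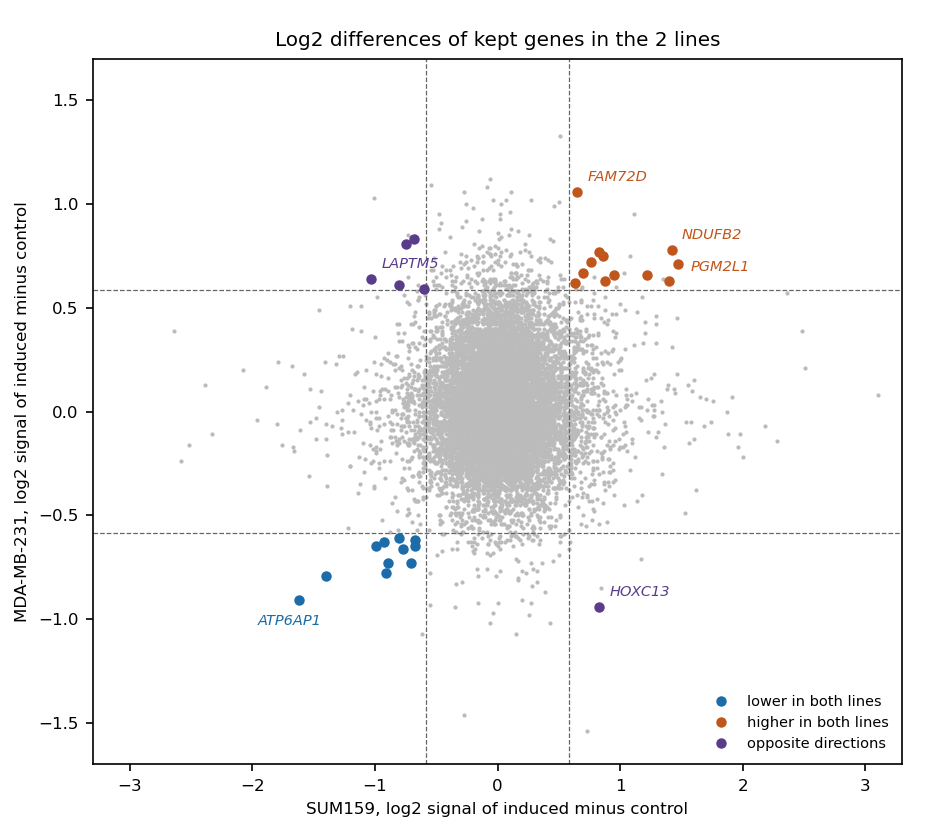
Log2 difference of induced minus control for the 14417 kept genes other than MIR100, in SUM159 (horizontal axis) and MDA-MB-231 (vertical axis), with 1 array per group. Dashed lines mark 1.5-fold; coloured points are the named genes lower in both lines, higher in both, or in opposite directions, and ATP6AP1 lies at -1.62 and -0.91.

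Genes reported or predicted as miR-100 targets fell as a list over both lines. Camera gave this list an adjusted p of 5.15e-06 with the preset correlation, and the adjusted p was 0.822 with an estimated correlation and 0.757 by fry. Of 27 kept members, 18 were lower in both lines and 2 higher in both, and the median difference was -0.14 in each line, at the 0.38th percentile of matched lists in SUM159 and the 0.055th in MDA-MB-231. Among the 18, FGFR3, TTC39A, GRHL1 and PPFIA3 had signals of 3.96 to 4.42, near the cutoff. Their differences lay between -0.11 and -0.02, so their signs say little. Across all kept genes, 50.9% of the nonzero pairs of differences had the same sign in both lines. The strongest members were CTDSPL and SMARCD1, then MTOR, which encodes the kinase of the mTOR complexes (-0.37 and -0.66), and TRIB2 (-0.64 and -0.31). Not all followed: PLK1 stood at 0.55 and -0.12, IGF1R at 0.32 and -0.37, and THAP2 and MBNL1 were slightly higher in both lines. The list was drawn from general knowledge of this microRNA, without sequences.

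ATF4-dependent amino acid and stress response genes also fell as a list. Camera's adjusted p was 5.21e-07, against an adjusted p of 0.822 with an estimated correlation and 0.757 by fry. Of 27 kept members, 15 were lower in both lines and 1 higher in both, with medians of -0.37 in SUM159 and -0.25 in MDA-MB-231, each at percentile 0 of the 10000 matched lists. The stress cytokine gene GDF15 stood at -1.22 and -0.56, NUPR1 at -1.01 and -0.36, the amino acid transporter gene SLC7A1 at -0.67 and -0.62, and the mTORC1 inhibitor gene DDIT4 at -0.97 and -0.25. The transcription factor gene ATF4 itself was at 0.20 and -0.32. In SUM159, 8 members were past 1.5-fold lower and 1, STC2, past it higher, and in MDA-MB-231 2 were past it lower.

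The metallothionein list, made of 8 genes for these metal-binding proteins and the zinc exporter gene SLC30A1, rose over both lines. The adjusted p by camera was 6.67e-05, and it was 0.822 with an estimated correlation and 0.785 by fry. Of its 9 kept members, 7 were higher in both lines and 0 lower in both, with medians of 0.37 in SUM159 (99.9th percentile) and 0.29 in MDA-MB-231 (99.8th). MT1F stood at 1.00 and 0.52, SLC30A1 at 0.42 and 0.54, MT1H at 0.48 and 0.32, and MT2A at 0.46 and 0.30. The metallothioneins are close paralogs, so their probesets are not independent, and with the signal cutoff at the 75th percentile 5 members were left and the adjusted p was 0.159.

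Mitosis genes rose by camera, with 12 of 25 members higher in both lines and 2 lower in both. The adjusted p was 0.00738 by camera, 0.822 with an estimated correlation and 0.757 by fry. Their medians were 0.15 in SUM159 and 0.16 in MDA-MB-231, at the 89.8th and 94.4th percentiles, which lie inside the range of matched lists. CCNA2, which encodes cyclin A2, stood at 0.53 and 0.53, the cell-cycle kinase gene CDK1 at 0.72 and 0.39, DLGAP5 at 0.76 and 0.21, and KIF20A at 0.75 and 0.21. The camera call was also lost after quantile normalization (adjusted p = 0.166), with the cutoff at the 75th percentile (0.101) and without the block (0.189).

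The other 19 lists that were tested did not pass camera's adjusted threshold, and in all 23 lists 0 members passed when p was adjusted over the list alone, as over all genes. The NF-kB and inflammatory cytokine list had an adjusted p of 0.106, which became 0.0178 after quantile normalization, where the adjusted p was 0.929 with an estimated correlation and 0.897 by fry. Over both lines, DNA replication genes had a median of 0.01 and a mean of -0.05, with CDC6 at -1.08 and -0.23. Cholesterol synthesis genes had a median of 0.02 and a mean of 0.00, and glucocorticoid response genes a median of -0.04 and a mean of 0.05; camera's direction was down for the first and second of these lists and up for the third, so median and test differed in sign. Interferon response genes had medians of -0.08 in SUM159 and 0.05 in MDA-MB-231, with IFIT2 at -0.95 and 0.17 and XAF1 at 0.10 and 0.52. Nuclear-encoded respiratory chain genes had medians of 0.11 and -0.04, with 0 of 31 members past 1.5-fold in either line. Ribosome biogenesis genes stood at 0.18 and -0.04, lysosome and autophagy genes at 0.10 and -0.06, and NRF2 oxidative stress genes at 0.07 and -0.01 (medians in SUM159 and MDA-MB-231).

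Chromatin remodelling genes of the ISWI and SWI/SNF families had medians of -0.05 in SUM159 and 0.04 in MDA-MB-231, both inside the range of matched lists. SMARCD1 and SMARCA4 (-0.21 and -0.56) were lower in both lines, whereas SMARCA1 was higher in both (0.97 and 0.60). Hypoxia and glycolysis genes had medians of 0.07 and -0.02, with the glucose transporter gene SLC2A3 at 1.20 and 0.38 and CA12 at 1.17 and -0.04. Among breast stem cell and pluripotency genes (medians -0.11 and 0.08), PROCR was higher by 1.29 and 0.46 and CD44 by 0.89 and 0.09, while the p53 target list (medians 0.02 and 0.03) held FAS at 0.93 and 0.47. Antigen presentation genes had medians of 0.08 and -0.01, Wnt targets of -0.06 and -0.01, and glucocorticoid response genes of -0.13 and 0.05 with DUSP1 at 1.29 and 0.33. Luminal epithelial genes had a median of -0.09 in each line, with GATA3 at -0.75 and -0.10. Markers of blood, endothelial and fibroblast cells had medians of -0.10 and -0.04.

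**Figure D3:**
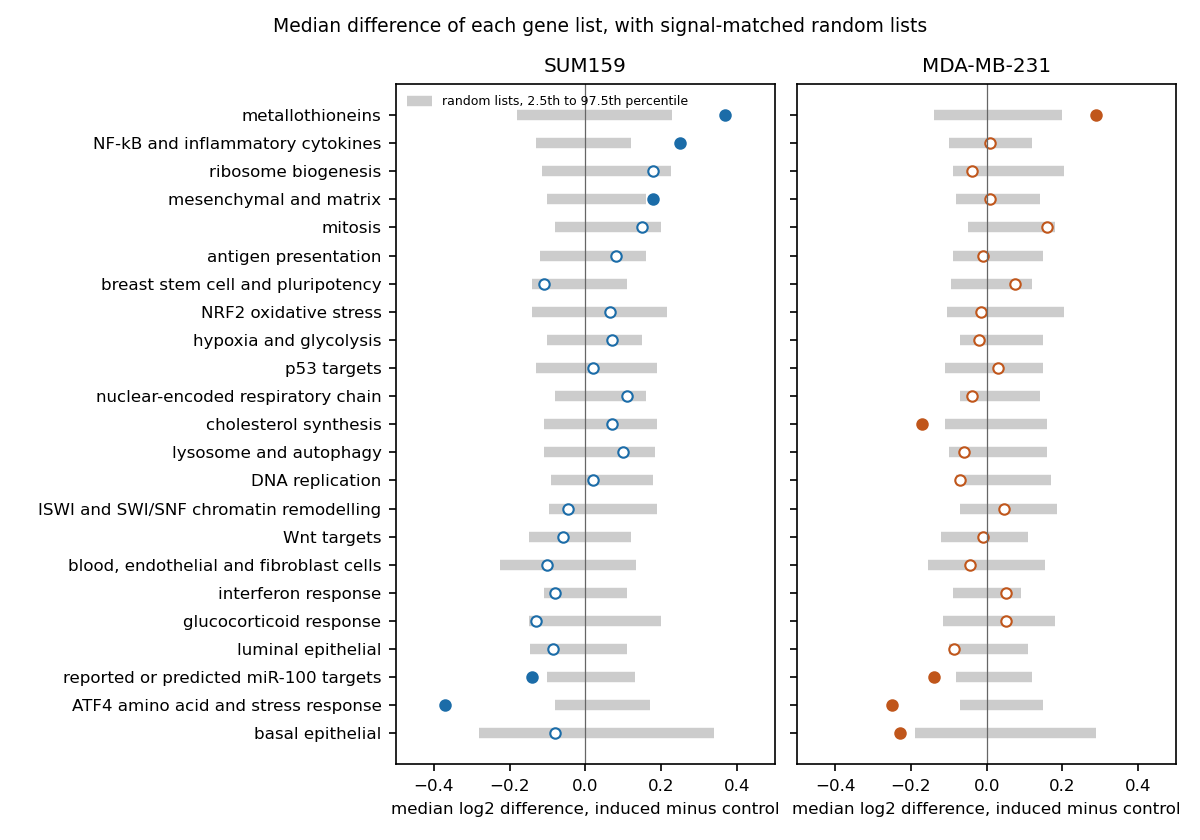
Median log2 difference (horizontal axis) of each of the 23 tested gene lists in SUM159 and MDA-MB-231; filled points lie outside the central 95% of 10000 signal-matched random lists, and grey bars span that range. The miR-100 target and ATF4 lists lie below it and the metallothionein list above it in both lines.

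The lines themselves differed widely before and after induction, and this comparison describes their background. Between SUM159 and MDA-MB-231, 2998 genes were higher in SUM159 and 3438 in MDA-MB-231 (limma, treatment as a block). The numbers were 3460 and 3420 after quantile normalization and 3236 and 3168 after centring, so which line had more depends on the scaling. The homeobox gene IRX2 was higher in SUM159 by 11.77 ± 0.12 log2 units (SE, n = 2 arrays per line, limma adjusted p = 0.00115), as was its divergent transcript IRX2-DT (10.16 ± 0.15). The 2 arrays of a line are 1 control and 1 induced array, not replicates. The aminopeptidase gene ANPEP (11.58 ± 0.13), CCAT1 (11.17 ± 0.36), TMPRSS15 (10.72 ± 0.23), the autotaxin gene ENPP2 (10.39 ± 0.12), the complement gene C3, ABI3BP, FEZ1 and CD109 were the others of the 10 highest. In MDA-MB-231, ANKRD1, a YAP target, was higher, at -12.07 ± 0.20 for SUM159 minus MDA-MB-231 (adjusted p = 0.00117). The cystatin genes CST4 (-9.03 ± 0.12) and CST1 (-7.99 ± 0.13), SLC43A3 (-8.76 ± 0.12), the Wnt antagonist gene DKK1 (-8.70 ± 0.13), PYGL (-8.46 ± 0.18), the matrix protease gene MMP14 (-8.23 ± 0.12), STC1, PAPSS2 and ARHGAP29 followed. In the line where they were lower, ANPEP, CCAT1, ENPP2, FEZ1, CD109, CST4, DKK1 and PYGL had mean signals below 4.035, the cutoff, so their differences are lower bounds and their order is not fixed. These 20 genes had limma adjusted p between 0.00115 and 0.00243.

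By list, 23 of 27 ATF4 genes were higher in SUM159 at a limma adjusted p under 0.05, as were 14 of 23 mesenchymal and matrix genes, including CDH2 and COL6A3. In MDA-MB-231, 21 of 25 mitosis genes, 17 of 23 DNA replication genes and 10 of 16 luminal genes were higher at that threshold. The epithelial cadherin gene CDH1 lay at 3.77 to 4.03 on all 4 arrays, below the cutoff, while VIM lay at 15.20 to 16.23. Of 16 measured markers of blood, endothelial and fibroblast cells, 10 were below the cutoff; CD68 was the brightest, at 10.50 to 13.13, KDR lay at 5.33 to 6.01, and CD3E, DCN, LYZ and PDGFRA lay at or below 4.84. Without the block, leaving out the MDA-MB-231 control array gave 1581 genes higher in SUM159 and 2198 in MDA-MB-231, and leaving out the induced MDA-MB-231 array gave 1620 and 2064.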

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

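All results in this part were singled out after the differences were seen, and none of the differences between lines was tested, since the design leaves no residual degrees of freedom for them. The genes below stood past 1.5-fold in opposite directions in the 2 lines, with 1 array per group.

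The homeobox gene HOXC13 was higher by 0.83 in SUM159 and stood at -0.94 in MDA-MB-231, so the differences of the lines were 1.77 apart. The GTPase gene RAP2B stood at -0.75 and 0.81 (-1.56 apart, SUM159 minus MDA-MB-231), SLC10A5 at -0.68 and 0.83 (-1.51), and the lysosomal membrane protein gene LAPTM5 at -1.03 and 0.64 (-1.67). SPAST, which encodes the microtubule-severing protein spastin, stood at -0.80 and 0.61 (-1.41), and DCAKD at -0.60 and 0.59 (-1.19). The 17 genes that went opposite ways set beside 4.47 and 7.31 for independent lists (5 higher in SUM159, 12 higher in MDA-MB-231) leave open that single genes here reflect array noise.

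Among the probesets with no gene symbol, 3 differed by more than 2 log2 units the same way in both lines. Probeset 47419795_st was above its control signal by 4.48 in SUM159 (7.38 to 11.86) and by 3.69 in MDA-MB-231 (6.16 to 9.85). Probeset 47422337_st was lower, at -3.56 and -2.99, and 47422896_st at -2.08 and -5.87. What these probesets measure is not known here.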

How the results depend on the processing

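Protein-coding genes alone, leaving out MIR100 and leaving out the 3 lowest targets were chosen after seeing the data; the other alternatives were planned. Counting at 2-fold gave 105 higher and 84 lower genes in SUM159, 15 and 6 in MDA-MB-231, and 1 (MIR100) and 0 the same way in both, since the bound is stricter. The 113 lower genes in MDA-MB-231 (0.784% of genes) became 69 (0.771%) with the signal cutoff at the 75th percentile and 58 (0.488%) with protein-coding genes only. The 22 genes higher in both lines (0.153%) became 12 (0.101%) with protein-coding genes only. Both settings test fewer genes, which does not account for the lower shares among protein-coding genes. The Pearson r of 0.111 was 0.0268 without MIR100 and 0.0305 with protein-coding genes only, so it rested on MIR100. In SUM159, the 570 higher and 432 lower genes were 471 and 515 after quantile normalization, and between lines 2998 and 3438 became 3460 and 3420, so neither balance held. No alternative gave a gene an adjusted p under 0.05 over both lines. The 373 higher and 183 lower genes at an unadjusted p under 0.05 were 316 and 279 after quantile normalization, 562 and 436 without the filter, 223 and 90 with the cutoff at the 75th percentile, and 11 and 6 without the block, whose residual then holds the difference between lines. Leaving out each array in turn, without the block, gave 1 to 9 and 0 to 5. Between lines it gave 1581 to 2696 genes higher in SUM159 and 2064 to 2868 in MDA-MB-231; with the block, 3 arrays leave no residual degrees of freedom. All 4 list calls were lost with an estimated correlation (adjusted p = 0.822 each) and by fry (0.757 for miR-100 targets, ATF4 genes and mitosis, 0.785 for the metallothionein list). Both of these rarely called simulated shifts, but the simulated genes were drawn independently. The simulation thus does not favour the preset for lists whose members vary together. Mitosis was also lost after quantile normalization (0.166), with the cutoff at the 75th percentile (0.101) and without the block (0.189), the metallothionein list with that cutoff (0.159), and NF-kB genes passed after quantile normalization (0.0178, but 0.929 with an estimated correlation and 0.897 by fry); the cause was not tested. The target and ATF4 lists kept their call under every rescaling, filter, probeset and block alternative. Of 259 values of named genes under an alternative, 242 moved by at most the spread of probesets below the cutoff (0.19 log2 units in SUM159, 0.18 in MDA-MB-231, their mean over both) and 259 kept their sign. Genes ranked for large differences could hardly change sign, so the kept signs say little. Signal over background limits what single low probesets show: below the cutoff, 3.39% were past 1.5-fold in SUM159 and 2.34% in MDA-MB-231. The seed-site comparison was not run, as it needs transcript sequences. The fit over both lines pairs the arrays by cell line; the labels give no replicate numbers for another pairing.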

Other observations

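The tests of the full target and ATF4 lists repeated in this part were planned, but their use to weigh explanations was not. All other tests in this part were chosen or narrowed after results were seen. The MAPK output and YAP target lists were written after some of their members' values had been seen. The tests of noise, of these 2 lists and of the 3 lowest targets, and the bounds that decide on YAP and mTORC1, replaced earlier versions once those had been read. A group of genes that report on MAPK (ERK) signalling stood higher in induced SUM159 cells. Beyond DUSP5, these included DUSP6 (0.89), DUSP4 (0.60), ETV4 (0.70), FOSL1 (1.55), IER3 (1.56) and PHLDA1 (1.60), while SPRY2 (-0.39) and ETV5 (-0.30) were lower. In MDA-MB-231, DUSP6 stood at 0.24, DUSP4 at -0.27 and ETV4 at -0.39, and the median of all 16 genes was -0.09, against 0.56 in SUM159. The values of EGR1, FOSL1, IER3, PHLDA1 and CCND1 had been seen when the list was written, so the 0.56 partly reflects that choice. Without these genes and DUSP5, the median of the other 10 was 0.36 in SUM159 and -0.155 in MDA-MB-231. YAP target genes went both ways in SUM159: CCN1 (0.90), NUAK2 (0.86) and MYOF (0.71) were higher, and RBMS3 (-1.32), TGFB2 (-1.22) and CRIM1 (-1.01) lower.

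Of 27 genes reported or predicted as miR-100 targets, 18 were lower in both lines, some of them only slightly and near the signal cutoff. The list was called lower by camera (adjusted p = 5.15e-06) but not with an estimated correlation (adjusted p = 0.822) or by fry (0.757). A shift that depends on signal level is argued against, because the list lay at or below the 0.38th percentile of signal-matched lists in both lines. That a few strongly lowered members alone carry camera's call is argued against, since without CTDSPL, SMARCD1 and MTOR the adjusted p was 0.000693 for the other 24, against 0.822 with an estimated correlation and 0.785 by fry. Exposure to the drug without miR-100 stays open and cannot be told apart from the microRNA, since 0 arrays of cells given the drug lacked the construct. Repression of these transcripts by miR-100 is a hypothesis in line with the list's direction, and it remains untested against the drug.

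Of 27 ATF4 amino acid and stress response genes, 15 were lower in both lines, and the list was called lower by camera (adjusted p = 5.21e-07) but not with an estimated correlation (adjusted p = 0.822) or by fry (0.757). A shift that depends on signal level is argued against (percentile 0 in both lines). MTOR was lower in both lines, and mTORC1 promotes ATF4 output, so lower mTORC1 output across its transcript programmes may be considered. This stays open in both lines: cholesterol synthesis and ribosome biogenesis genes lay at the 65.3rd and 93.1st percentiles in SUM159, inside the range of matched lists, and at percentiles 0.1 and 9.9 in MDA-MB-231. Medium and nutrient state of single cultures, and the drug itself, also stay open, as they were not measured.

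More genes were past 1.5-fold in SUM159 than in MDA-MB-231 (1002 against 357). Independent random noise of single probesets in the SUM159 pair stays open for part of the excess: below the signal cutoff the share past 1.5-fold was 1.45 times that in MDA-MB-231, against 2.81 times among kept genes. Handling of the 1 culture or array per group cannot be told apart from the induction. Higher MAPK pathway output in induced SUM159 cells is a candidate explanation that was examined on these pathway genes only. The 10 members, without DUSP5 and the 5 whose values had been seen, had a median of 0.36, at the 99.7th percentile. Of these, 7 were higher and 3 were past 1.5-fold higher. So short a list cannot show how much of the excess, if any, goes with the pathway. In MDA-MB-231 they lay lower, at -0.16 and the 1.51st percentile. Higher YAP target expression stays open, since the 17 targets whose values had not been seen went both ways (median -0.03, 15.8th percentile), and all 22, with 5 chosen when their values were known, had a median of 0.21, at the 98.5th; in MDA-MB-231 the 17 lay at the 1.67th.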
